A study of Drosophila melanogaster with 8 samples.

How the data were processed

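The libraries hold cDNA of Drosophila melanogaster, strain Oregon R, sequenced as long reads after amplification of the 5′ and 3′ ends of qtc transcripts with gene-specific RACE primers, per the labels' protocols. Eyes, heads and salivary glands were sampled from females and males, and ovaries and testes once each. Flies were reared at 25 °C and collected 5 to 7 days after hatching, per the labels' protocols, which describe the isolation of heads, eyes and testes; that of salivary glands and ovaries is not given in the sources used here. Each of the 8 groups has 1 library. The groups were taken from the tissue and sex in the labels, and no separate cultures or repeat libraries are named, so p-values measure the spread between tissues or sexes and not between replicate animals.

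The authors deposited estimated counts for 31089 transcripts in each library, which need not be whole: 39.7% to 57.3% of the values above 0 in a library were fractional. The authors also deposited TPM for the same transcripts, corrected for length and summing to 1000000 in each library, and these were used only to check that they follow from the estimated counts. A second deposited table gives whole-number counts of total, filtered and mapped reads per library and of reads mapped to the qtc locus. Minimap2, Salmon and edgeR and the genome build BDGP6 are named per the submitters' processing notes, without versions or roles; the filter applied to the reads is not given in the sources used here. The share of each qtc transcript rests on the authors' assignment of reads to transcripts that share exons. Reads had a mean length of 524 to 647.7 bases before the filter, against 1890 to 2791 exonic bases in a qtc transcript. A read of mean length thus does not span a transcript, and shares by transcript or class are estimates. Reads were not re-aligned here, and counts of overlapping genes, on either strand, and near-identical copies are uncertain.

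Transcript IDs were matched to the BDGP6 annotation, release 115. Of the 31089 IDs, 31048 matched and 41 did not, and the unmatched ones held 0.094% to 0.535% of a library's estimated counts and stayed out of gene sums and tests. Estimated counts were summed over 14292 genes and rounded to whole numbers. Rows named as rRNA pseudogenes took 1.94% of the counts in ovaries and 23.86% in female eyes; they have near-identical copies, so their counts are uncertain, and they stayed in the totals unless stated.

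A library held 262332 to 334257 reads, of which 90780 (testes) to 156627 (female eyes) passed the authors' filter, and 88471 to 152222 estimated counts. At this depth, a count of 3, the limit that a count of 0 allows, corresponds to 19.7 to 33.9 counts per 1000000. Binomial (Wilson) and exact Poisson intervals are at 95% and, because PCR reads without molecular identifiers are not independent molecules, these intervals and floors cover counting error only. Folds against a library at 0 were computed against 3 counts in that library, and folds against 1 to 3 counts carry the exact binomial interval of the counts.

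For each library the share of qtc counts assigned to each of the 12 annotated qtc transcripts was computed with its Wilson interval. The female minus male difference in share was taken within eyes, heads and salivary glands and compared with all sign changes of the 3 differences (exact two-sided permutation, smallest possible p = 0.25). Transcripts were also grouped by the start of the first exon, by a cassette exon and by 3′ end, a grouping chosen after seeing the data.

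Gene counts of the 6 somatic libraries were fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood F test) as tissue plus sex, with genes kept by filterByExpr at a minimum count of 10, which left 1316 genes. This additive model has 2 residual degrees of freedom and takes the deviation of each tissue from a shared sex difference as its error. Adjusted p-values are from the Benjamini-Hochberg method with a threshold of 0.05. Transcript usage was tested with edgeR's diffSpliceDGE in the same design on 565 transcripts of 245 genes. Fold changes are log2 with a standard error (SE) from the same fit. Gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 counts per 1000000 (CPM) with a prior count of 2, at a preset correlation of 0.01, with an estimated correlation, and with fry, where 3 or more members were tested; genes of chromosomes X and 4 were added as lists. The lists cover yolk proteins, male head genes, dosage compensation, sex determination, eggshell, female germline, spermatogenesis, Y-linked genes, male accessory gland, phototransduction, eye pigment, salivary gland, neuron, glia, fat body, muscle, digestive enzymes, chemosensory appendage, hemocyte, antimicrobial peptides, heat shock and stress, mitochondrially encoded genes, cytosolic ribosomal proteins and the circadian clock.

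Ovaries were compared with testes, and females with males within a tissue, as log2 ratios with a prior count of 2 and TMM scaling over all 8 libraries, with no test because each group has 1 library. Genes at 4-fold or more were counted where the higher library had at least 50 counts. A list's median was set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. Correlations of sex differences between tissues are across genes with at least 20 counts in the higher library of each pair, and genes are not independent replicates.

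Named genes follow a rule fixed before the data were examined. qtc is always named. For a fitted comparison the rule takes the 10 largest changes in each direction among genes past the threshold and moving the same way in every pair, or, where fewer than 10 pass, those passing and the 5 of smallest p in each direction. It adds up to 4 members of each list by smallest adjusted p. For single-library comparisons it takes the 10 largest ratios in each direction with at least 50 counts and up to 4 members of each list with the highest counts. For usage it takes the 10 genes of smallest adjusted p and qtc, Sxl, tra, dsx, fru and msl-2 where measured, and for levels the 5 genes with the largest share of a library. Genes named outside this rule are said to be so.

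Alternatives were DESeq2 1.42.0, library totals without TMM, no count filter, all 8 libraries, limma-voom, qtc left out, transcripts as features, models without the tissue or sex term, and leaving out each library or tissue in turn. Leaving out the rRNA-named genes was added after seeing the data. Each fit was tested on simulated data with known changes. For the shared sex difference, run on 1167 simulated genes, 49.2% of genes changed 4-fold and 98.4% of genes changed 16-fold were recovered, and 0.51% of unchanged genes were called. For eyes against heads (1148 genes) the shares were 15% and 87.7%, for salivary glands against heads (1208 genes) 18.8% and 86.4%, and for usage (247 genes) 75% of genes with a 16-fold change of 1 transcript. Apart from the planted change, the simulated libraries shared 1 mean per gene or transcript. They held no other tissue differences and no sex differences that vary by tissue, so recovery in the real data can be lower. Tables were handled with pandas and intervals with scipy.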

Results

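Long-read cDNA enriched for transcripts of quick-to-court (qtc), a gene named for its effect on male courtship, was counted in eyes, heads and salivary glands of female and male flies and in ovaries and testes. The series title puts the question as whether qtc is spliced differently in the sexes. Each of the 8 tissue and sex groups has 1 library, of 88471 (testes) to 152222 (female salivary glands) estimated counts, with 3674 to 5138 genes above 0 and 836 to 1108 genes at 10 counts or more. There are no replicates within a group, so every spread given is between tissues or between sexes.

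The most abundant named genes differed by tissue. Arr2, an arrestin of photoreceptors, took 10.31% of the counts of male eyes, 4.48% of female heads, 4.43% of male heads and 2.42% of female eyes. Rh3, a rhodopsin, took 5.07% of male eyes. Cp15, a chorion protein of the eggshell, took 8.22% of female eyes. In salivary glands the fat body list, led by the larval serum protein gene Lsp2, took 18.7% of the counts of females and 18% of males. An rRNA-named pseudogene, 28SrRNA-Psi:CR45859, was the most counted of the eye, head and testis libraries, at 19.28% in female and 17.05% in male eyes, 6.69% in female and 10.29% in male heads and 4.6% in testes. VhaAC39-1, a subunit of the vacuolar proton pump, took 4.74% of female heads and 5.11% of male heads, and RpL36A 8.51% of female and 6.74% of male salivary glands. Cp15 took 15.59% of ovaries and CG34425 2.32% of testes.

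The qtc gene (FBgn0028572) lies on chromosome 2L from 5060815 to 5070750, plus strand, in BDGP6. Its 12 annotated transcripts start at 4 positions, and a first exon is named here by its start. First exon 5060815 belongs to qtc-RA, RE and RF, and 5062972 to RI and RL. First exon 5064372 belongs to RB, RG and RH, and 5066012 to RJ, RK, RM and RN. The last ends at 5066167 in RJ and RM and at 5066071 in RK and RN. A coding cassette exon of 93 bases, from 5069127 to 5069219, is present in 6 transcripts and skipped in 5. The remaining transcript, RH, ends upstream of it at 5068803. RJ, RK, RM and RN end with a separate exon from 5070353 and a coding end at 5070437, where the other transcripts that pass the cassette end coding at 5070300.

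**Figure D1:**
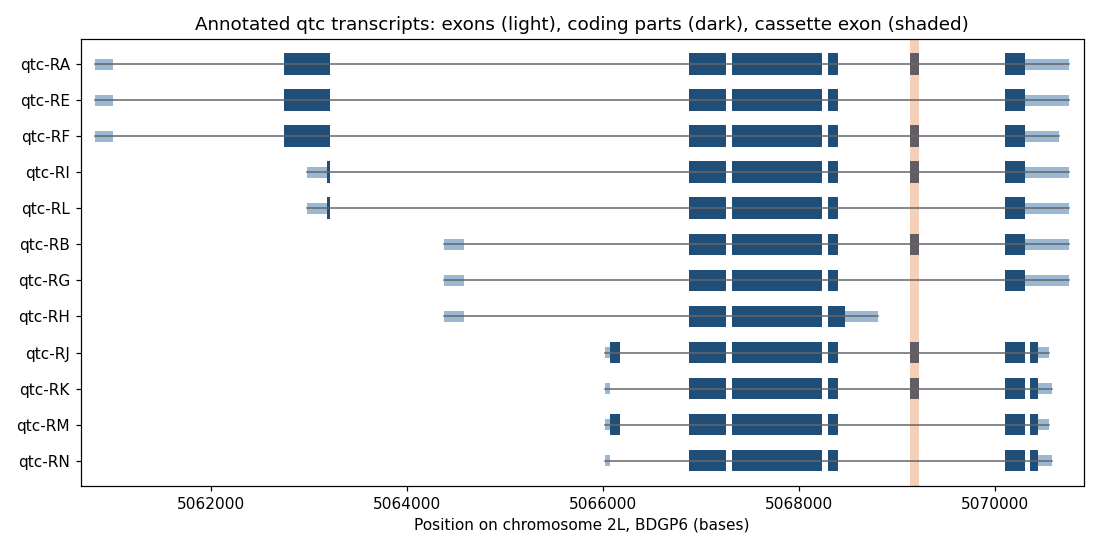
Annotated qtc transcripts on chromosome 2L of BDGP6, with position in bases on the horizontal axis. Thin light boxes are exons, tall dark boxes are coding parts and the shaded band is the cassette exon from 5069127 to 5069219, which 5 transcripts skip.

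Of the mapped reads, 8% in male eyes (Wilson interval 7.86% to 8.15%) and 7.29% in male heads (7.16% to 7.43%) fell at the qtc locus, against 0.937% in female eyes (0.889% to 0.988%) and 3.36% in female heads (3.26% to 3.45%). Salivary glands had 2.23% in females and 1.74% in males, ovaries 1.08% and testes 4.69%. Because qtc was enriched with its own primers, these shares are levels in amplified libraries, not in the tissues. Counts of all other genes come from the same amplified libraries, so their levels and folds describe these libraries too. The qtc transcripts received 24.2% to 65.8% as many estimated counts as there were reads at the locus.

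By estimated counts the leading transcript was RI in male eyes and both head libraries and RA in both salivary gland libraries. It was RH in female eyes, RN in ovaries and RL in testes. RI lies wholly within the exons of RA, and RL within those of RE. Reads within RI or RL do not tell these pairs apart by sequence, and the Wilson intervals do not cover this uncertainty. In male eyes qtc-RI took 79.8% of the qtc counts (78.4% to 81.1%) and in female eyes 5.16% (3.93% to 6.85%), where qtc-RH took 76.8% (73.9% to 79.4%) and qtc-RN 14.4% (12.2% to 16.8%). In heads, RI took 44% in females and 41.6% in males and RB 42.5% and 28.4%. RA took 5.34% in female and 21.4% in male heads. In salivary glands RA took 29.7% in females and 54.4% in males, RE 24.8% and 13% and RH 1.87% and 20.3%. Ovaries had 59.7% RN (55.3% to 63.8%), 21.6% RE and 16.9% RF, and testes 53.7% RL (50.8% to 56.6%), 13.6% RN and 9.99% RM. RL was at 0 in every other library, which allows a share of up to 0.09% in male eyes and up to 0.6% in ovaries.

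**Figure D2:**
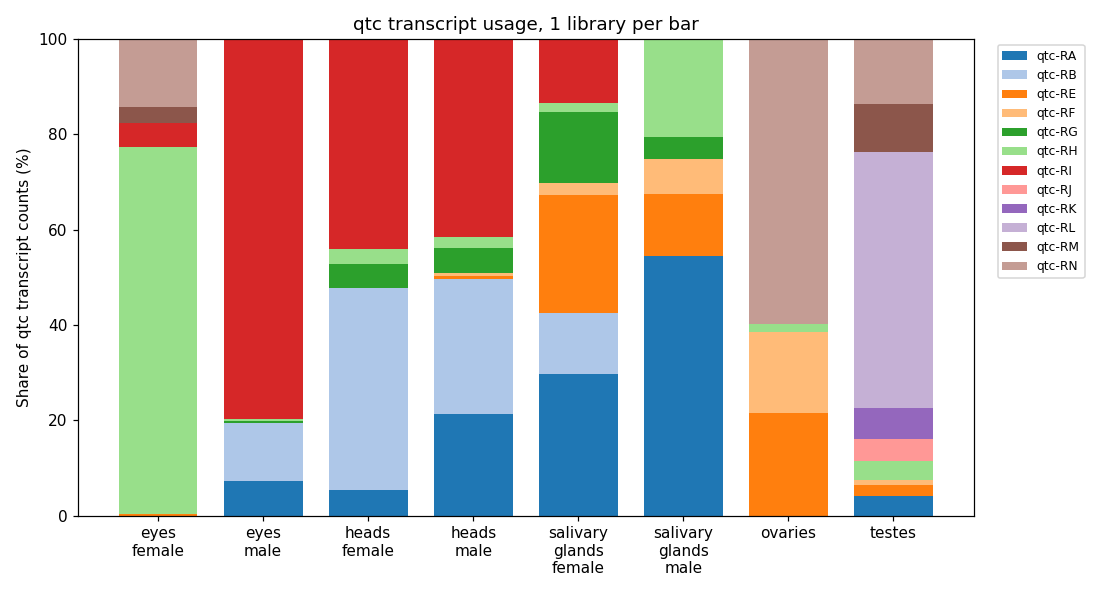
Share of qtc transcript counts in percent (vertical axis) assigned to each annotated transcript, 1 bar per library. The leading transcript is RH in female eyes (76.8%), RI in male eyes (79.8%), RN in ovaries (59.7%) and RL in testes (53.7%).

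The cassette exon was included in 99.5% of the counts of transcripts that reach it in male eyes, 94.9% in female heads and 94.1% in male heads. These are shares of estimated counts by transcript, not of reads seen to cross the cassette exon. Salivary glands included it in 59.6% (females, 56.3% to 62.8%) and 77.5% (males, 73.4% to 81.1%), and gonads in 17.2% (ovaries) and 17.1% (testes). Female eyes included it in 22.2% (17.3% to 28.5%), over 209.7 counts. The 46.6 counts with the exon there were all RI. Of the 163.1 counts without it, 129.9 were RN and 29.2 RM, which start at 5066012, and 3.9 were RE. RNA of ovaries in this library is not excluded as the source of RN and RM. The low inclusion in female eyes thus need not be a change of cassette splicing in the eye. First exon 5066012 was used by 59.7% of counts in ovaries, 34.8% in testes and 17.6% in female eyes. It was at 0 in male eyes, both head libraries and female salivary glands, and at 1.4 counts in male salivary glands.

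No transcript passed a test of a sex difference shared by the somatic tissues. qtc-RA was lower in females in all 3 tissues, by -7.26, -16 and -24.72 percentage points (eyes, heads, salivary glands; mean -15.99 ± 8.73 SD, n = 3 tissues; exact sign-flip permutation p = 0.25, adjusted p = 1 over 12 transcripts). RF, at under 8% in each somatic library, differed by -0.65 points in heads and -4.78 in salivary glands (mean over 3 tissues -1.83 ± 2.58 SD; same exact p = 0.25), with no direction in eyes, where it had 0 and 1.7 counts. The smallest p that 3 pairs allow is 0.25. RH differed by 76.49 points in eyes, 1.01 in heads and -18.41 in salivary glands, and RI by -74.63, 2.42 and 13.44. By first exon, 5064372 differed by 63.98, 14.73 and 4.44 points and 5060815 by -6.97, -17.15 and -17.64, each with an exact permutation p = 0.25. For 5064372 the salivary gland intervals overlap (26.6% to 32.5% in females, 21.6% to 28.7% in males), so that tissue gives no clear direction. The split of RA from RI, and of 5060815 from 5062972, rests on the assignment of reads in exons that these transcripts share. In the share of usage that differs between libraries, the sexes were 94.4% apart in eyes, 48.1% in salivary glands and 17.5% in heads, and ovaries and testes were 81.2% apart.

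The same question was asked of every gene with 2 or more measured transcripts. None of 245 genes passed a test of transcript usage between the sexes (edgeR diffSpliceDGE, 10 genes at an unadjusted p under 0.05; Simes combination 0, with 4 unadjusted). The smallest adjusted p was 0.416, for Men, a malic enzyme, followed by Atf3 and Capr at 0.555. CG11334, Klp68D, Klp98A, RanBP3 and mys stood at 0.766, and Spn42Da and CG2924 at 0.965. qtc, with 7 transcripts tested, had an adjusted p of 0.995. Sxl, tra, dsx, fru and msl-2, genes of sex determination and dosage compensation, were not among the genes tested.

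Genes that differ between the sexes were sought across eyes, heads and salivary glands. The gene of smallest p was Yp2, a yolk protein gene, which was higher in females. It was at 3383.6 counts per 1000000 (CPM, scaled over the 6 somatic libraries) in female and 17.5 in male eyes. In heads it was at 1239.7 in females and 0 in males, and in salivary glands at 8.9 and 0. Over the 3 tissues Yp2 was 296-fold higher in females (counting interval 81.5 to 2450, 620 against 2 counts; log2 fold change 8.07 ± 1.01 SE, edgeR adjusted p = 0.146). Yp1 was 219-fold higher (60.4 to 1820) and Yp3 36.9-fold (12.3 to 181), with 0 or 1 count in each salivary gland library. None of 1316 genes passed (edgeR, 34 at an unadjusted p under 0.05; DESeq2 called 2, Yp1 and Yp2, both higher in females, and limma-voom 0). Other genes of smallest p were, higher in females, the protease gene Jon99Fii, 244-fold (43.4 to 9680), the amylase gene Amy-p, at least 4.56-fold over 0 in the male libraries, and ND-75 (3.06 ± 0.826). Jon99Fii had 245 counts in female eyes against 0, 11 in female heads against 1 and 0 in salivary glands, and Amy-p 34 and 11 in female eyes and heads and 0 in female salivary glands, so both came mostly from the female eye library. Higher in males were ple, Pepck1 (-3.08 ± 0.905), l(3)80Fj (-2.03 ± 0.618), trio (-2.45 ± 0.742) and Lon (-2.12 ± 0.669). Their adjusted p was 0.961, and that of Yp3 0.905. ple, which encodes tyrosine hydroxylase, was higher in males in eyes and heads (-2.38 ± 0.648), with 144 counts against 36 in eyes and 78 against 14 in heads, while 2 against 0 in salivary glands give no direction. qtc was at -0.82 ± 0.602 (adjusted p = 0.961), lower in females in eyes and heads and higher in salivary glands.

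As groups, 3 of 3 yolk protein genes were higher in females (3 past the threshold adjusted over the list alone, 0 over all genes; camera adjusted p = 0.000775). Cytosolic ribosomal protein genes were higher in females for 58 of 67 (median 0.47, camera adjusted p = 2.61e-06), with RpL41 at 2.48 ± 0.78 and RpL22 at 0.99 ± 0.499. Digestive enzyme genes were higher for 6 of 7 (median 2.53; 2 adjusted over the list alone, Amy-p and Jon99Fii, and 0 over all genes; camera adjusted p = 0.0172). By tissue they were higher in females for 12 of 12 in eyes and 3 of 3 in heads, at 10 counts or more, and lower for 5 of 6 in salivary glands (median -1.37). Phototransduction genes were lower for 20 of 21 (median -0.88, camera adjusted p = 0.000775), among them Gbeta76C at -1.48 ± 0.685 and rdgA at -1.24 ± 0.692. This came mostly from the eyes, with 24 of 24 lower in females (median -1.69), against 13 of 23 in heads (median -0.24) and under 0.02% of counts in salivary glands. No ribosomal or phototransduction gene passed adjusted over the list alone. Each of these 4 calls was lost, with adjusted p = 0.884 with an estimated correlation and 0.859 by fry. In the eyes the female library held 1.35% digestive enzyme counts and the male library 0.00318%, and the eggshell list took 8.35% and 0.0241%. The salivary gland, neuron, glia, fat body, muscle, heat shock, mitochondrially encoded and clock lists and chromosomes X and 4 were not called (camera adjusted p from 0.229 to 0.965). The X-linked genes had a median of 0.06 over 223 genes, with 1, Yp2, past the threshold adjusted over the list alone and 0 in the other lists not called. The heat shock list had a median of -0.05 and a mean of -0.03 while camera placed it higher in females. Of lists with 1 or 2 members tested, msl-3 of dosage compensation was at 1.13 ± 1.03, snf of sex determination at 0.85 ± 0.661, Cp15 of the eggshell at 1.37 ± 1.91, CycB and stau of the female germline at 4 ± 2.92 and -1.04 ± 0.643, and Pka-R1 and Act87E of the spermatogenesis list at -1.54 ± 0.752 and -1.01 ± 0.869. The pigment gene g was at 0.85 ± 0.861, Obp83a of the chemosensory list at -2 ± 1.07 and Nplp2 of the hemocyte list at 0.73 ± 0.589. No member of the male head, Y-linked, accessory gland and antimicrobial peptide lists passed the count filter.

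Eyes were compared with heads, which contain eyes. Muscle genes were lower in eyes for 11 of 12 (median -1.16), with wupA, a troponin, at -4.23 ± 1.12 and Tm1, a tropomyosin, at -2.69 ± 0.711. Neuron genes were lower for 9 of 9 (median -1.57), among them para, a sodium channel, at -2.79 ± 0.963. Phototransduction genes went both ways, with retinin at 2.62 ± 0.942 and the ocellar rhodopsin Rh2 at -2.5 ± 0.902 (median 0.45, mean 0.09). The sexes moved apart here: the list took 5.5% of the counts of female eyes against 9.73% of female heads, and 19.7% of male eyes against 10.3% of male heads. Genes of smallest p were CG16826 (8.31 ± 1.17), Pgant1 (4.05 ± 0.646), whe, at least 54.7-fold higher in eyes over 0 in both head libraries, 18SrRNA-Psi:CR41602 (3.38 ± 0.621) and the odorant binding protein gene Obp83a, at least 12.9-fold higher. Lower in eyes were ITP, at least 20.8-fold, mrt (-3.19 ± 0.629), CG46448 (-4.5 ± 0.848), phu (-4.23 ± 0.81) and Cyp6a8 (-3.65 ± 0.789). None passed over all 1316 genes (edgeR smallest adjusted p = 0.24, with 175 at an unadjusted p under 0.05; DESeq2 called 33 and limma-voom 0). Without the female eye library 77 genes passed, and without the male eye library 150. Without the male salivary gland library 3 passed, CG16826, whe and, named after its value was seen, Phae2, all higher in eyes. qtc was at 0.1 ± 0.7 (adjusted p = 0.962), and turned to -0.33 with library totals in place of TMM. Without the female eye library it was 0.98, and without the male eye library -0.9.

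By list, neuron (camera adjusted p = 0.000596) and muscle (0.0125) were lower in eyes, and cytosolic ribosomal protein (4.78e-07; 56 of 67 higher) and mitochondrially encoded genes (0.0351; 6 of 6 higher) were higher. As shares of all counts, ribosomal genes took 11.7% of female eyes against 11.8% of female heads, and 6.88% against 9.48% in males. Mitochondrially encoded genes took 0.143% against 0.162% in females and 0.373% against 0.116% in males. All 4 calls were lost, with adjusted p = 0.906 with an estimated correlation, and fry gave 0.244 to 0.623. Adjusted over the list alone, 2 muscle genes (wupA and Tm1, lower), 2 glia genes (alrm lower, e higher), 1 heat shock gene, Hsp27 at 3.04 ± 0.761, and 1 gene of chromosome 4, ATPsynbeta at -2.48 ± 0.654 and named after its value was seen, passed, and 0 over all genes. Cp15 (6.96 ± 2.86) and Obp83a were the only members tested of their lists, so a p over the list alone is unadjusted there. Cp15 rested on female eyes, with 11807 counts against 25 in male eyes. Of lists with 1 or 2 members tested, Cp15 and Obp83a passed over the list alone. msl-3 (2.24 ± 1.15), snf (-1.04 ± 0.816), CycB (3.82 ± 2.37), stau (-0.31 ± 0.753), Act87E (-2.52 ± 1.01), Pka-R1 (-0.33 ± 0.837), g (-0.46 ± 0.954) and Nplp2 (-0.39 ± 0.697) did not. The digestive enzyme and heat shock lists were higher for 7 of 7 and 8 of 8, each with a camera adjusted p = 0.052. Jon65Aiii was at 1015.9 CPM in female eyes, 8.7 in male eyes and 0 in both head libraries. The yolk, phototransduction, salivary gland, glia, fat body and clock lists and chromosomes X and 4 were not called (camera adjusted p from 0.173 to 0.894). The clock list had a median of 0.92 and a mean of -0.46, with camera lower, and the glia list a median of 0.54 and a mean of -0.08, with camera higher.

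Salivary glands differed most from heads. The stage of the gland donors is not given in the sources used here. A difference of tissue is therefore not told apart from a difference of stage. Of 1316 genes 354 passed (edgeR), 179 higher and 175 lower in salivary glands, and 353 of them moved the same way in both sexes. Glue protein genes of the larval salivary gland rose: Sgs5 was 2330-fold higher (counting interval 644 to 19200; 1705 and 1356 counts in female and male glands, 2 and 0 in heads; adjusted p = 0.0115), and Sgs4 was at least 104-fold and Sgs1 at least 80.2-fold higher. Of 13 salivary gland genes 13 were higher and 12 passed over all genes and adjusted over the list alone. Larval fat body genes rose with them: Lsp1gamma was at least 361-fold, Fbp2 at least 94.8-fold and Lsp1alpha at least 82.1-fold higher, and Lsp1beta rose by 9.1 ± 1.09. CG12715 and veil were at least 335-fold and 79.7-fold higher. CG14265 was 1250-fold (346 to 10400) and Eig71Ee 1360-fold higher (244 to 53800). In the same libraries the fat body list took 18.7% and 18% of the counts, against 0.448% and 0.524% in heads.

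Most phototransduction and neuron genes fell. Phototransduction genes were lower for 21 of 21, of which 18 passed over all genes and 21 adjusted over the list alone: Arr2 fell by 9.6 on the log2 scale (SE 0.983, adjusted p = 0.01), Rh3 was at -9.89 ± 1.38, and with 1 count in glands Rh4 was 1570-fold (282 to 62200) and Ggamma30A 1110-fold lower (199 to 44000). ninaE, the main rhodopsin, was at least 70.4-fold, Rh2 at least 62.5-fold, Cpr72Ec at least 63.2-fold and Cpn at least 76.4-fold lower. Cyp313a1 and the clock neuropeptide gene Pdf were at least 24.8-fold and 25.2-fold lower, and EbpIII was 1080-fold lower (194 to 42900). Of 9 neuron genes 7 fell, with Syx1A at -5.06 ± 0.795, and 1, Syt1, rose (3.19 ± 0.787), named after its value was seen; 8 fell and 1 rose adjusted over the list alone. qtc was at -0.97 ± 0.711 (adjusted p = 0.326), at -1.57 without the female eye library, where it passed, and at 0.05 without the male salivary gland library. Its adjusted p ranged from 0.0204 to 0.975 over the alternatives.

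Camera called 9 lists: phototransduction (adjusted p = 1.62e-10), salivary gland (3.94e-07), cytosolic ribosomal proteins (7.43e-06; 65 of 67 higher, 5 passing, RpS3, RpS3A, RpL36A, RpL26 and RpL37A, and 0 adjusted over the list alone), muscle (0.000546; 6 of 12 fell, 9 adjusted over the list alone), neuron (0.00222), fat body (0.00829; 8 rose and 2, FASN1 and Tsf1, fell, also adjusted over the list alone), heat shock and stress (0.00829; 4 of 8 rose, Hsp27, Hsp23, Hsp83 and Hsc70-3, and 6 adjusted over the list alone), glia (0.0317; e and alrm of 3 fell, and 3 adjusted over the list alone) and clock (0.0398; Pdf and Pdp1 fell, also adjusted over the list alone). With an estimated correlation none held: adjusted p = 0.415 with an estimated correlation for 7 of them, 0.434 for ribosomal proteins and 0.645 for fat body, and fry called 6. Hsp27 (6.15 ± 0.801) and Hsp23, 61.3-fold higher (20.5 to 302), small heat shock protein genes, rose, as did RpS3 (2.15 ± 0.5) and RpL36A (1.75 ± 0.474). Of 7 digestive enzyme genes 3 rose, Jon65Aiv, Jon65Aiii and deltaTry, the last at least 25.8-fold, and 4 adjusted over the list alone, with epsilonTry, with a camera adjusted p = 0.19. Of the yolk genes Yp2, 129-fold lower (22.9 to 5120) with 0 counts in both male libraries, and Yp3, at least 3.33-fold lower, fell (3 adjusted over the list alone, with Yp1, camera 0.264). mt:ATPase6 fell by 2.44 on the log2 scale (0 adjusted over the list alone, mitochondrial list 0.835). The X-linked genes had 30 higher and 28 lower calls (28 and 28 adjusted over the list alone; median 0.13, mean -0.38, camera lower, adjusted p = 0.912), and on chromosome 4 RpS3A rose and unc-13 and dpr7 fell, also adjusted over the list alone (0.5). The chromosome 4 genes were named after their values were seen. Nplp2 of the hemocyte list fell (-3.15 ± 0.756, adjusted p = 0.0304). Act87E (-3.27 ± 1.1) passed adjusted over the list alone but not over all genes. So did g, 7.01-fold lower (2.19 to 35.8), but as the only member of its list tested its p over the list is unadjusted. Cp15 (0.13 ± 1.8), msl-3 (1.71 ± 1.23), snf (0.25 ± 0.771), stau (-0.97 ± 0.793), CycB (3.94 ± 3.08) and Pka-R1 (-1.03 ± 0.912) did not pass, and Obp83a was at 0 on both sides.

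The balance of higher and lower calls moved with scaling and with other choices. Library totals without TMM gave 105 higher and 270 lower, DESeq2 164 and 259, and leaving out rRNA-named genes 114 and 201. The median of all genes moved from 0.14 with TMM to -0.58 with library totals and -0.22 with DESeq2, and for eyes against heads from 0.06 to -0.33 and -0.02, and for the sex difference from -0.03 to -0.06 and -0.16, so changes of a list are relative to these. The sign of the median of each list tested by camera, chromosomes, for which this was not computed, aside, was the same with TMM, library totals and DESeq2. Without 1 library, 40 (female salivary glands) to 637 (male eyes) genes passed, with 81 without male salivary glands, 140 and 201 without female and male heads, and 623 without female eyes; 112 passed with all 8 libraries and 0 with transcripts as features.

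Ovaries and testes, 1 library each, were compared as ratios without a replicate check. Eggshell genes stood out in ovaries: Cp15 was at 118000 CPM, scaled over all 8 libraries as in the rest of the text (exact Poisson interval 117000 to 120000) and at 431 in testes (314 to 577). Femcoat was 209-fold higher in ovaries (counting interval 37.3 to 8270) and Cp38 60.9-fold (16.7 to 506). Of 10 eggshell genes 10 were higher in ovaries (median log2 ratio 3.59, or 2.98 with zeros at the floor; at the 100th percentile of random lists). Spermatogenesis genes were lower in ovaries for 18 of 18 (median -3.49, or -3.35 with zeros at the floor; percentile 0): loopin-1 was 602-fold higher in testes (107 to 23900), and Mst98Ca was at least 149-fold and ocn at least 129-fold higher in testes. Female germline genes had a median of 2.28 (1.23 with zeros at the floor; percentile 95.6), with fs(1)N 89.2-fold higher (15.8 to 3540) and zpg, an innexin gene, 59.8-fold (10.5 to 2380). Ribosomal protein genes were higher in ovaries for 68 of 70 (median 1.99, percentile 100).

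Of 516 genes with 50 or more counts in either gonad, 63% differed by 4-fold or more, 153 higher in ovaries and 172 in testes. The median of these genes was 0.51, and 0.67 with library totals; each list named here kept its sign under totals. Largest in ovaries were Cp15, RpL35, at 5700 CPM against 4 counts, Femcoat, CG4045, 64.3-fold (42.4 to 103), epsilonTry, dhd, Cbs, Jabba, CG31517 and superdeath, the last 4 at least 35-fold, 30.3-fold, 28.7-fold and 28.2-fold. epsilonTry, a trypsin, was at least 54.4-fold and dhd, a germline thioredoxin, at least 48.4-fold higher. Largest in testes were CG34425, at least 1300-fold, Eglp1, at least 1250-fold, CkIIbeta2, at least 850-fold, CG33704, at least 823-fold, CG6980, at least 699-fold, CG15283, 2300-fold (412 to 90900), CG4375, at least 527-fold, tomboy40, at least 407-fold, CG34434, at least 405-fold, and CG9592, at least 393-fold. In testes 5 accessory gland genes had 10 counts or more, against 0 counts in ovaries, with Acp26Aa at 230 CPM (147 to 342; at least 15.2-fold). Of the Y-linked genes FDY had 4 counts and Pp1-Y1 and Pp1-Y2 1 each in testes. The X-linked genes had a median of 1.23 over 245 genes (1.07 with zeros at the floor; percentile 100). The digestive list, with 5 genes, had a median of 3.01 (1.88 with zeros at the floor; percentile 99.4). The mitochondrially encoded list had a median of 0.28 and a mean of -0.08. Yp2 was 72.9-fold higher in ovaries (20 to 605), msl-3 had 58 and 45 counts and snf 56 and 39, and the other lists had fewer than 3 members at 10 counts or more. Fat body, muscle, heat shock and mitochondrially encoded lists lay at percentiles 16.3, 15.9, 53.8 and 71.3, and the accessory gland list at 13.7. qtc was at 2530 (2310 to 2760) in ovaries and 10600 (9980 to 11200) in testes.

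Within tissues, the female and male libraries differed most in eyes. With 1 library each, a difference between the sexes is not told apart from a difference between libraries. The eye libraries also had the lowest mapped shares of filtered reads, 93.55% in females and 89.74% in males, against 98.63% or more in the others. Of 337 genes with 50 counts or more, 30.9% differed 4-fold between female and male eyes, against 5.6% of 301 in heads and 8.8% of 306 in salivary glands. Female eyes held digestive genes: Jon25Biii was at least 318-fold, CG17571 at least 185-fold and Jon99Fii at least 73.6-fold higher, and 12 of 12 digestive genes were higher (median 4.9, or 4.02 with zeros at the floor; percentile 100). Cp15 was at 94500 CPM in female eyes against 25 counts in male eyes, RanBP3 485-fold higher (166 to 2360), and CycB, CG12057, CG3868 and CG10472 were at least 95.6-fold, 93.5-fold, 79.4-fold and 70.9-fold higher. Phae2 was 339-fold higher (60.5 to 13400). Higher in male eyes were CG43901, 431-fold (77 to 17100), Camta, at least 45.8-fold, Lsp2 (1378 counts against 31), CG32432, 34.4-fold (9.12 to 290), px, 21.1-fold (6.86 to 105), Cyp313a1, CG33110, SF2, CG14314 and Gfat1, the last 5 at log2 ratios of -3.92 to -3.33. Phototransduction genes were lower in female eyes for 24 of 24 (median -1.69, percentile 0), and the eggshell (median 4.7, or 4.27 with zeros at the floor), female germline (3.41, or 2.44) and ribosomal (0.88) lists were at percentile 100. The yolk list was at 5.52 (99.7). Mitochondrially encoded (-1.89, percentile 0), salivary gland (-3.12, or -2.26 with zeros at the floor; 0.1), fat body (-1.55; 0.6) and muscle genes (-0.98; 3.6) were lower in female eyes. Neuron, glia, chemosensory, heat shock, clock and X-linked genes lay at percentiles 11 to 93.2, the clock list with a median of -1.14 and a mean of 0.08. The median of all genes with library totals in place of TMM went from 0.48 to 0.44 in eyes, 0.18 to 0.04 in heads and -0.05 to -0.08 in salivary glands.

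In heads, Mst98Ca, a gene of the spermatogenesis list, was at least 171-fold higher in females, and Yp1 and Yp2 were at least 122-fold and 73.3-fold higher. CG15283, CG14070 and CG17575 were at least 34.4-fold, 31.4-fold and 18.7-fold higher in females, and dmGlut, IBIN, Polr2H and eIF3b followed at log2 ratios of 3.2 to 2.26. The yolk list had a median of 6.65 (6.2 with zeros at the floor; percentile 100), the spermatogenesis list 2.29 (99.9) with betaTub85D 22.4-fold higher in females (3.59 to 930), muscle genes 0.71 (99.7), ribosomal genes 0.44 (99.7) and phototransduction genes -0.24 (2.6). Digestive genes had a median of 2.18 (66.2), and neuron, glia, fat body, heat shock, mitochondrially encoded and clock lists lay at percentiles 6.2 to 75.1, as did X-linked genes (0.08, or -0.05 with library totals). wol was 87.3-fold higher in males (15.3 to 3480), and CG45263, ple, poe, dikar, CG3223, Cyp313a1, CG15628, Npc2h and SERCA were higher in males at log2 ratios of -2.81 to -1.39. In salivary glands, ND-75, 45.2-fold (12.2 to 379), beta-Spec, 24.6-fold (6.5 to 208), robo2 (2.88), lva (2.49) and Sgs1 (2.35) were higher in females. CG32302, 49.9-fold (16.7 to 245), l(2)efl (-4.57), Pcp, 25.3-fold (8.3 to 126), Act57B (-3.78), CG10912 (-3.71) and CG18179 (-3.66) were higher in males, where 4 of 4 muscle genes were higher (median -2.95, percentile 0), as were 5 of 6 digestive genes (-1.37; 0.2), while fat body (0.47; 98.2) and ribosomal genes (0.21; 99.3) were higher in females. Salivary gland, heat shock, mitochondrially encoded and X-linked genes lay at percentiles 37.1 to 92.1. Across genes, the sex difference of eyes correlated with that of heads (Pearson r = 0.31, bootstrap interval 0.18 to 0.42, 500 genes) and of gonads (r = 0.37, 0.24 to 0.49). The female eye library held ovary genes such as Cp15, so the value with gonads need not show a sex difference shared by these tissues. The sex difference of eyes gave -0.13 with salivary glands (-0.26 to 0). The heads gave -0.08 with salivary glands (-0.21 to 0.04) and -0.2 with gonads (-0.37 to -0.03), where the Spearman rho was 0.02, and salivary glands 0.17 with gonads (0.04 to 0.29), over 6 correlations in all. Genes are not independent replicates.

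**Figure D3:**
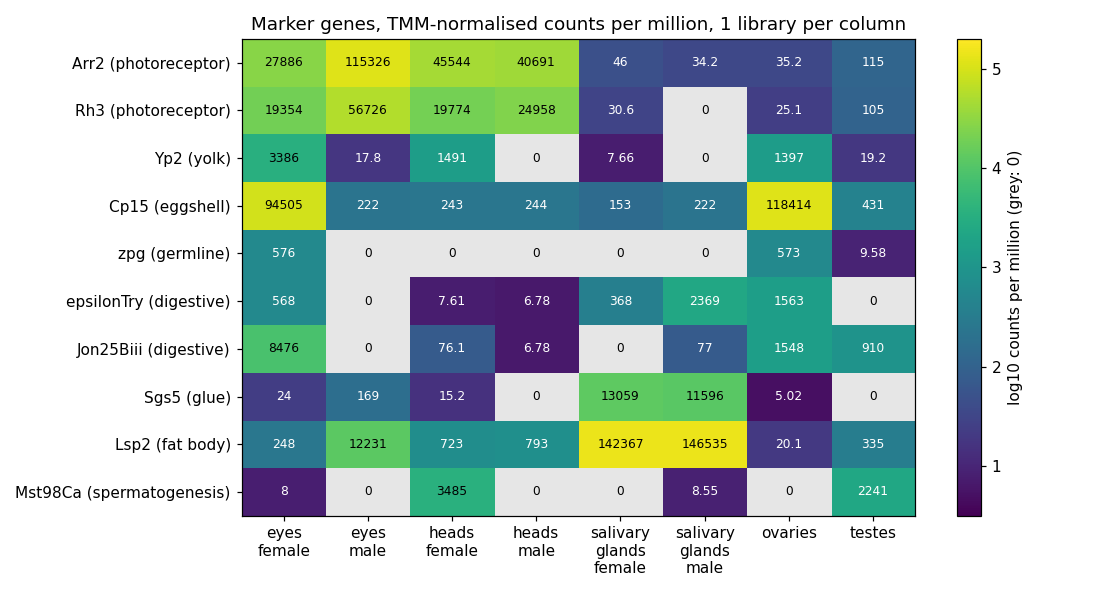
Levels of 10 marker genes, chosen after their values were seen, in CPM with TMM scaling over 8 libraries (number and colour, log10 scale, grey for 0), 1 library per column. Cp15 is at 94505 in female eyes and 118414 in ovaries and at 431 or less in the other libraries.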

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

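All tests of explanations in this part, the counts over other splits included, were written down after the results were seen. In 1 fit per tissue, with 1 residual degree of freedom, the female against male difference of a tissue was tested against that of the other somatic tissues. The spread in such a fit comes from the other 2 tissues, so these p-values do not cover variation between libraries of the tissue itself, which has 1 per sex. In the eyes it differed for 31 genes (edgeR, 26 higher and 5 lower; 179 at an unadjusted p under 0.05). Cp15 differed by 9.08 on the log2 scale (adjusted p = 0.000115), the trypsin gene epsilonTry by 11.58 and the fat body gene Lsp2 by -5.44. In the salivary glands it differed for 4 genes (59 at an unadjusted p under 0.05), CycB (-13.11), l(2)efl (-5.95), Phae2 (-8.81) and Jon25Biii (-15.42), the last 2 named after their values were seen, and in the heads for 0 (24 at an unadjusted p under 0.05; no other tool was run). Of these 4, CycB, Phae2 and Jon25Biii rest largely on the eye pair, with 318 against 0, 376 against 1 and 1059 against 0 counts in female and male eyes and 3 against 22, 50 against 78 and 0 against 9 in salivary glands, while l(2)efl had 50 against 1105 in salivary glands. CycB, epsilonTry and Jon25Biii include libraries at 0, so these sizes depend on the prior count.

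The female eye library held ovary and gut genes far above the male eye and both head libraries. Against reads of the ovary library assigned to it, 11 of 29 ovary-restricted genes (37.9%) departed from 1 common ratio (exact binomial test at 0.01): Femcoat was at 2000 CPM in ovaries and 8 in female eyes, zpg at 573 and 576. Against expression in the eye itself, the median ratio of female heads to female eyes was 24 times higher for 19 phototransduction genes (1.8, lower quartile 1.16) than for 10 eggshell and female germline genes (0.0752, upper quartile 0.204). RNA of the gut stays open, since 17 of 19 digestive enzyme genes (89.5%) were higher in female than in male eyes, with Jon25Biii at 8480 CPM against 0, but this rise prompted the explanation and cannot test it. Ovary RNA stays open too. Of 19 eggshell and female germline genes, 16 (84.2%) were highest in female eyes among the somatic libraries, but this rise also prompted its explanation and cannot test it. Femcoat, at 1 count in female eyes, and CG14309, at 0, depart from the composition of the ovary library. A difference between the sexes was not told apart from a difference between the female and male eye libraries.

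In the female eye library qtc-RH took 76.8% of qtc counts and first exon 5066012 took 17.6%. The level of qtc-RH was 335.6 times that expected from the pooled ratio of ovary-restricted genes to ovaries (0.364, quartiles over genes 0.127 and 0.804). The qtc primers did not target those genes, and enrichment may differ between libraries, so multiples from this ratio do not by themselves weigh ovary RNA. Within qtc, RH had 694.4 counts and RN 129.9 in female eyes, against 9.1 and 300.4 in ovaries. Uneven amplification aside, this balance argues against ovary RNA as the source of RH. The level of qtc-RM was at least 42.68 times that expected, with 29.2 counts against 0 in ovaries. RM and RN share most exons, so their split rests on the assignment of reads. Transcripts starting at 5066012 had 159.2 counts in female eyes and 300.4 in ovaries. The first exon of RM runs to 5066167 and that of RN to 5066071, so only reads over the differing parts tell them apart. Whether reads covered these parts is not known here, so ovary RNA as the source of RM is not settled. The female minus male difference in RH share was -18.41 points in salivary glands, against 76.49 in eyes and 1.01 in heads. These libraries thus showed no direction common to the somatic tissues. With 1 library per sex and tissue, and intervals of counting error only, a shared difference is not excluded. For qtc-RN, the other transcript starting at 5066012 seen in female eyes, the observed level was 1.89 times that expected, within the bound set. It had been looked at before the test was written, and a ratio of genes that were not enriched need not hold for qtc. Ovary RNA as the source of RN stays open. A difference special to the eye, and amplification from few molecules, were not tested.

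Mst98Ca was at 3485 CPM in female heads and 0 in male heads. Testis RNA as its only source is argued against by 16 other spermatogenesis genes, 3 of them with a ratio of female heads to testes above 0.1, whose median ratio was 0.0026, against 1.55 for Mst98Ca. Some testis RNA in this library stays open: of 319 testis-restricted genes, 157 (49.2%) had a count in female heads and 70 (21.9%) in male heads, with CG15283 at 700 CPM in female heads, 0 in male heads and 11600 in testes. This set was not held low in heads. Some members were counted in both head libraries, such as twin, with 13 counts in testes, 13 in female heads and 9 in male heads, and some are accessory gland genes, such as Acp26Aa. Such genes enter both shares. Whether the 319 genes keep 1 ratio to testes, as testis RNA needs, is not settled, since 66 (20.7%) departed from it by exact binomial tests at 0.01, which cover counting error only and not the added spread of PCR. No biological explanation was tested.

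Reads at the qtc locus that exceed the qtc transcript counts entered no comparison. They were 34.2% of the locus reads in female eyes, the lowest of the 8 libraries, and 75.8% in male salivary glands, the highest.

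For the sex difference shared by the somatic tissues the real split gave 0 genes and the highest other 23. A real value of 0 fixes that 10 of 10 splits of the 6 libraries give as many. The 2 splits with 23 are the same fit, since both leave only the female against the male eye library once tissue is in the model, so the 23 rest on that 1 pair. For transcript usage, where the real split and the highest other gave 0, 10 of 10 splits give as many for the same reason. In both cases 10 splits are too few for a share under 0.05.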

How the results depend on the processing

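The alternatives without rRNA-named genes and the grouping of qtc transcripts were chosen after seeing the data. Genes called for the sex difference went from 0 to 2 with DESeq2 and 9 without the count filter, and stayed at 0 with the others. For eyes against heads 0 became 33 with DESeq2, 38 without the filter and 0 to 150 when 1 library was left out (77 without female eyes, 150 without male eyes, and 3, CG16826, whe and Phae2, without male salivary glands). For salivary glands against heads 354 became 112 with 8 libraries, 0 with transcripts as features, and 40 to 637 when 1 library was left out: 40 and 81 without female and male salivary glands, 140 and 201 without female and male heads, 623 and 637 without female and male eyes. There the lone library of a tissue is assumed to vary like the others. Lists called fell from 4, 4 and 9 (sex, eyes, salivary glands) to 0 with an estimated correlation, and from 4 and 4 (sex, eyes) to 0 by fry. The log2 fold change of qtc in eyes against heads, 0.1, turned to -0.33 without TMM, -0.12 without the filter and -0.04 with 8 libraries, and ranged from -0.9 to 0.98 when 1 library was left out (-0.9 without male eyes, -0.02 without either head library). In salivary glands against heads it ranged from -1.95 to 0.05 (0.05 without male salivary glands). qtc transcripts with the same sign in each tissue compared, by sign alone and so with RF, which has no direction in eyes, went from 2 to between 3 and 4 without 1 tissue, where fewer tissues are compared. With a minimum of 20 or 100 counts, which changes the genes compared, 272 or 94 were 4-fold higher in ovaries and 344 or 96 in testes. For the other shifts the cause was not tested. The 6 correlations of sex differences stayed within their bootstrap intervals with library totals and with a prior count of 0.5. At this depth a qtc transcript under 0.09% to 0.6% of qtc counts is not told from 0.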

Other observations

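No explanation was tested in this part, and its genes were chosen after their values were seen. Both salivary gland libraries held glue protein and larval serum protein genes, and the age given in the labels is 5 to 7 days after hatching, while the stage of the salivary gland donors is not given in the protocols used here. Sgs5, a glue protein gene, was at 13059 CPM in females and 11596 in males, and at 169 CPM or less in the other libraries. Lsp2 was at 142367 and 146535 CPM and Lsp1beta at 54605 and 42537, and the salivary gland list took 2.9% and 2.58% of the counts. Lsp2 was also at 12231 CPM in male eyes and 248 in female eyes.

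Testes held 12 accessory gland genes at 3 counts or more, with Acp32CD at 182 CPM, and ovaries held 0. Male salivary glands held epsilonTry at 2369 CPM and PGRP-SC2 at 402, and female glands 368 and 61.3. Obp83a was at 399 CPM in male and 88 in female eyes and at 0 in the 6 other libraries. The antimicrobial peptide list took 0.0268% of female and 0.025% of male head counts. Of the male head genes, 3 were in the table, at 0.00598% of female and 0.00309% of male head counts.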
